A study of Azotobacter vinelandii with 15 samples.

How the data were processed

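RNA was measured by sequencing in 15 libraries of Azotobacter vinelandii, made from whole cells of the wild-type strain DJ grown in Burk's (B) medium with or without ammonium and of strain AZBB163 grown without it. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, treated with DNase, depleted of ribosomal and transfer RNA with a Ribo-Zero kit for Gram-negative bacteria, and sequenced as 100-bp paired-end reads on an Illumina HiSeq. The sample labels give the supplement as 20 mM NH4, while the series description gives 20 mM ammonium sulfate, which would hold more ammonium per litre, so the exact dose is left open.

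The values used are FPKM (fragments scaled by gene length and library size), in 1 table of the whole series that the authors deposited. Per the labels' protocols, the authors made them with a pipeline of a university computing centre (FastQC, Trimmomatic, an aligner, Cuffquant and Cuffnorm). Per the submitters' processing notes, Trimmomatic was version 0.33 and the aligner HISAT2 version 2.0.2, while the protocol text also names TopHat and Bowtie 2. The versions of FastQC, Cufflinks and Cuffnorm, the genome build, the annotation and the scaling option of Cuffnorm are not given in the sources used here. The table has no counts and no gene lengths, and whole reads were not recovered from it, so the depth behind each value is unknown and no counting intervals are given. The deposited FPKM do not add up to a fixed total: the highest sum of a library was several times the lowest, while the median over all rows lay between 62.5 and 74.2 FPKM. The sums follow a few abundant rows, since 108 locus tags in the highest blocks of tag numbers (called the high-numbered tags) took 59.3% to 86.8% of the FPKM of a library.

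The table holds 5159 gene rows, of which 1515 carry a gene symbol and 3644 only a locus tag. Symbols were used as the table gives them. The reference table at hand (assembly ASM3668736v1) does not list these locus tags, so it was matched by symbol only, for 742 of 1491 distinct symbols, and none of its coordinates were used. Rows with only a tag were not named, and, apart from members of a list, at most 2 rising and 2 falling tags are printed per comparison. The 22 symbols that occur on more than 1 row were kept apart by their order in the table. The planned exclusion of rRNA and tRNA genes, and the planned list of them, could not be applied as written, because no annotation of these tags was used here. The genes of the major nif region (nifH to nifF) and of the minor region (8 genes on either side of nifA) were taken from the run of locus tags in the table.

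An exact 0 in this table can be a failed estimate, since rows listed at 0 in some libraries reach at least 10000 FPKM in others (25 rows). Such rows stayed in the tests, are reported as listed at 0 and are given no fold change. In all, 514 rows were at 0 in at least 1 library, 215 of them in all libraries.

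All statistics were computed in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1). Every fold change is on that scale, which understates the change of weakly expressed genes. A gene entered the tests if its mean over the 15 libraries was at least 5 FPKM, which left 4872 genes (1509 with a symbol) and removed 287. For the comparisons at a given day, 1 linear model with 1 mean per strain, medium and time (9 groups) was fitted to all 15 libraries, with empirical Bayes moderation and a variance trend. The 4 groups with 1 library add nothing to the estimate of the spread and are assumed to vary like the others. For the comparisons over all times, 1 mean per arm was fitted (6 mutant, 5 wild-type and 4 ammonium libraries), so that differences between times within an arm count as spread. The arms hold different times (days 2 to 4, days 1 to 3, and 15 hours to day 2), so differences between times can also shift the arm means. The comparisons over all times do not part arm from time. Adjusted p-values are two-sided limma p-values after the Benjamini-Hochberg correction over the 4872 genes, and a gene was called (rose or fell) at an adjusted p under 0.05.

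The 27 gene lists, defined by symbol or region, were tested with limma's camera at a preset correlation of 0.01 between genes, corrected over the lists of a comparison, and again with a correlation estimated per list and with fry. Lists with fewer than 5 measured members (fix) were described without a test, and the gas vesicle list had 0 members. Members of a list were counted as called over all genes and also adjusted over the list alone. No list in any comparison passed camera with an estimated correlation, and that p is given beside each camera p under 0.05. The counts of called members and fry do not rest on the preset value.

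The comparisons, tests, filter, pseudocount, lists and most alternatives were chosen before the data were examined, as was the rule for the genes named. That rule always names nifL, nifA, nifH, nifD, nifK, nifB, vnfH, anfH, glnA and amtB. It adds the 8 largest rises and falls at day 2 (5 over all times and for day 2 against day 1) among called genes with at least a 2-fold change and at least 10 FPKM in the higher group, and, except over all times, with libraries that do not overlap between groups. From each list past its test it adds up to 3 members with the smallest adjusted p, and as many from other lists where a count is given. As many of the largest changes were tags without a symbol or rows at 0, the largest changes among genes with a symbol and no 0 are named instead, an adaptation made after the identifiers were seen. Genes named outside that rule are marked as chosen after their values were seen. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical in part. Replicate numbers are only the order of the samples and do not pair them.

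Alternatives changed 1 choice at a time: the pseudocount, the filter, the scaling of libraries (median centring, quantile normalization, equal sums), the variance trend, library quality weights, the series of library names (AV.RNAn, mRNAn.AV, AV.RNA.n) as a block, the libraries in the fit, and leaving out each library of the groups or arms compared. Calls said to be kept with each library left out, and ranges with 1 library left out, rest on those libraries. The other libraries also add to the shared spread, and such calls and ranges do not cover leaving them out. A few were added after the data were seen, among them the use of the ammonium libraries of 15 hours and day 1, or of the wild type of day 1, in place of day 2. The whole procedure was tested on simulated data for 4872 genes with the spread of the real ones, in which 200 genes were changed. For mutant against wild type at day 2 it recovered 42.0% of the 2-fold, 76.0% of the 4-fold, 84.0% of the 8-fold and 96.0% of the 16-fold changes, and 8.03% of its calls were unchanged genes. For wild type with against without ammonium at day 2 it recovered 28.0%, 64.0%, 90.0% and 90.0%. Of the 2-fold changes it recovered 18.0% for day 4 against day 2 in the mutant and 24.0% for day 2 against day 1 in the wild type. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.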

Results

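Azotobacter vinelandii is a soil bacterium that fixes nitrogen with a molybdenum nitrogenase (encoded by nifHDK) and holds vanadium (vnf) and iron-only (anf) nitrogenases as alternatives. NifL is the protein that restrains NifA, the activator of the nif genes. The libraries compare a strain whose nifL gene carries an insertion of about 500 bp (the mutant) with the wild type, which was grown without and with ammonium. There are 6 mutant libraries (3 at day 2, 1 at day 3 and 2 at day 4), 5 of the wild type without ammonium (2 at day 1, 2 at day 2 and 1 at day 3) and 4 of the wild type with ammonium (1 at 15 hours, 1 at day 1 and 2 at day 2). The depth of the libraries is unknown. Of 5159 genes in the table, 4872 were tested.

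The altered gene itself set the mutant apart in each library. nifL stood at 4526, 4498 and 3766 FPKM in the mutant at day 2, 4298 at day 3, and 5725 and 6429 at day 4. In the wild type without ammonium it stood at 69.4 and 55.2 FPKM at day 1, 49.0 and 48.9 at day 2, and 66.5 at day 3. With ammonium it stood at 46.3 FPKM at 15 hours, 49.3 at day 1, and 127 and 78.7 at day 2. nifA, the next gene, lay between 108 and 196 FPKM in the mutant, 94.0 and 152 in the wild type without ammonium, and 87.2 and 273 with it. nifH, which encodes the iron protein of nitrogenase, lay between 40031 and 114350 FPKM in the mutant, 1937 and 4126 in the wild type without ammonium, and 62.9 and 248 with it.

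**Figure D1:**
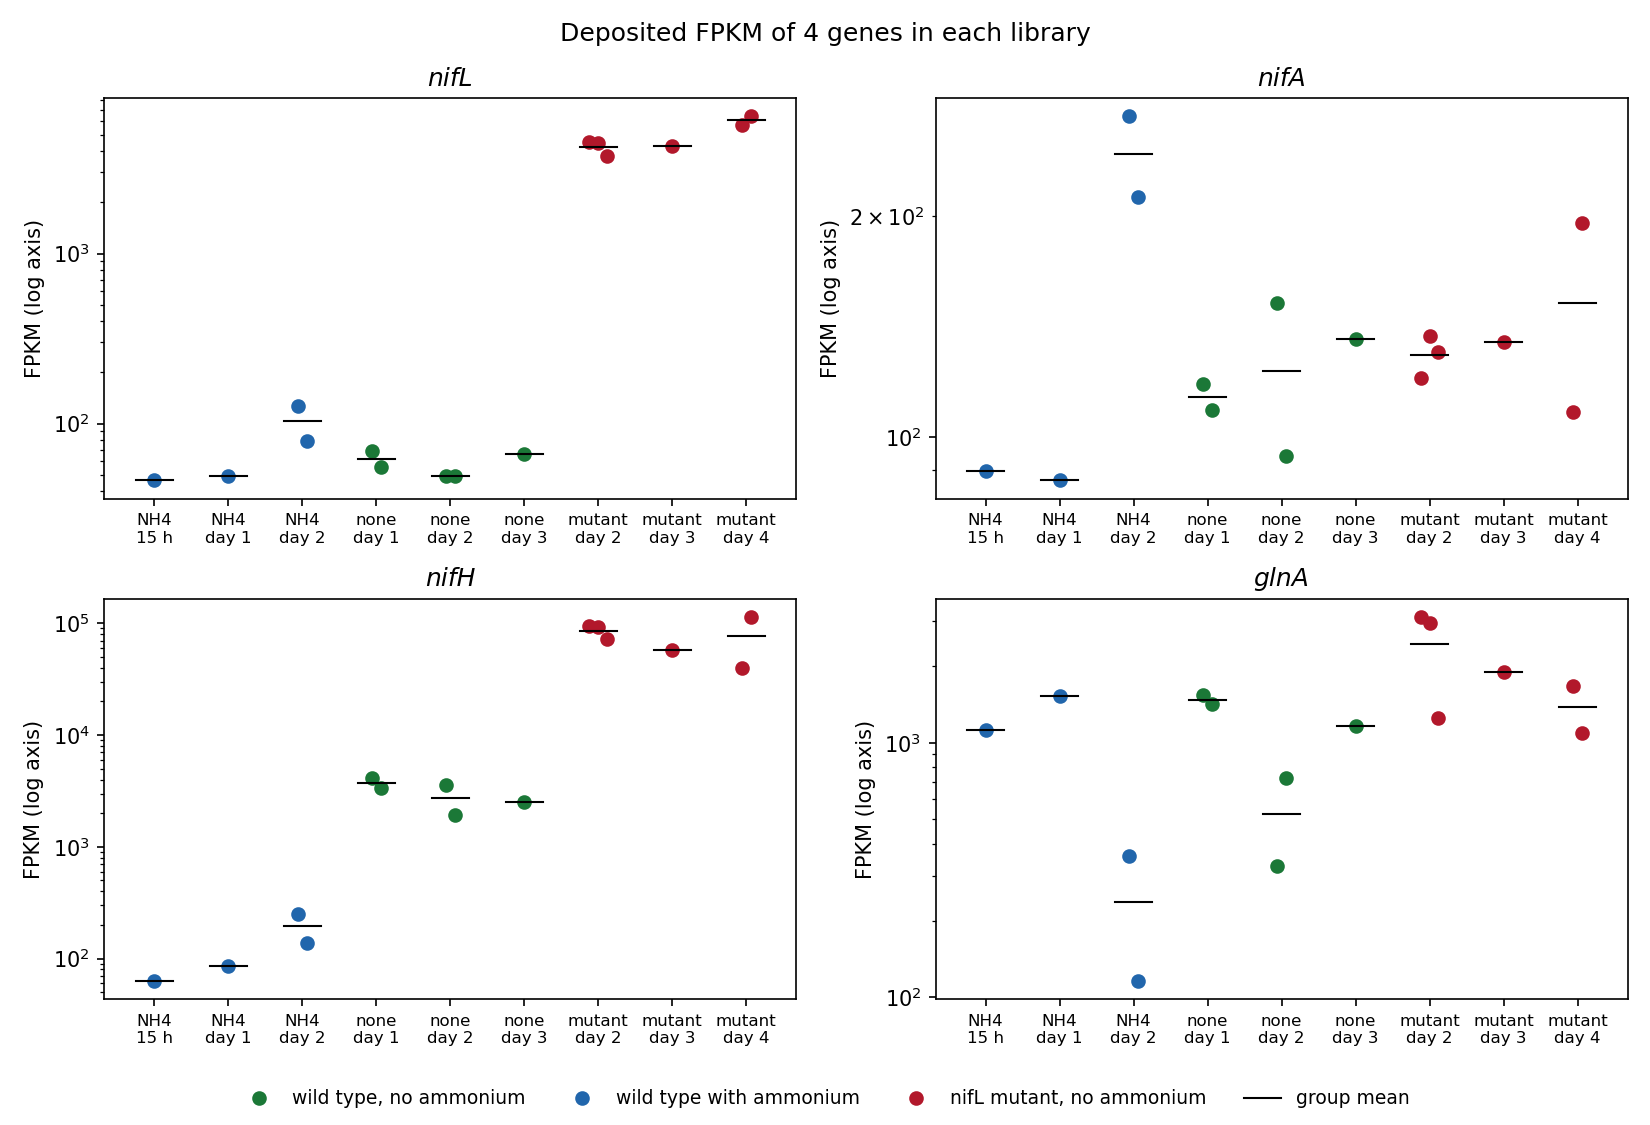
FPKM on a log axis of nifL, nifA, nifH and glnA in each of the 15 libraries, with 1 point per library, coloured by strain and medium, and a line for each group mean. nifL is at least 3766 FPKM in the mutant libraries and at most 127 FPKM in the others.

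The mutant libraries and the ammonium libraries of day 2 stood apart, while the earlier ammonium libraries lay near the wild type without ammonium. On the first principal component (29.8% of the variance) the mutant libraries lay between -52.7 and -27.5, the wild type without ammonium between -7.3 and 26.4, and the ammonium libraries at 26.9 (15 hours), 16.9 (day 1), 75.5 and 71.8 (day 2). On the second component (16% of the variance) the mutant libraries lay between 4.5 and 39.8, and the ammonium libraries of day 2 at 45.0 and 35.5. The wild type without ammonium lay between -35.1 and -18.4 there, and the earlier ammonium libraries at -24.85 (15 hours) and -27.8 (day 1). The third (9.15%) set the 3 libraries of the name series mRNAn.AV apart: wild-type day 2 replicate 1 lay at 46.4, mutant day 2 replicate 3 at 39.9 and mutant day 3 at 26.6, and the other 12 at 5.85 or below. Replicates of a group correlated across genes at 0.826 to 0.902 on the log2 scale, where genes are not independent replicates.

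**Figure D2:**
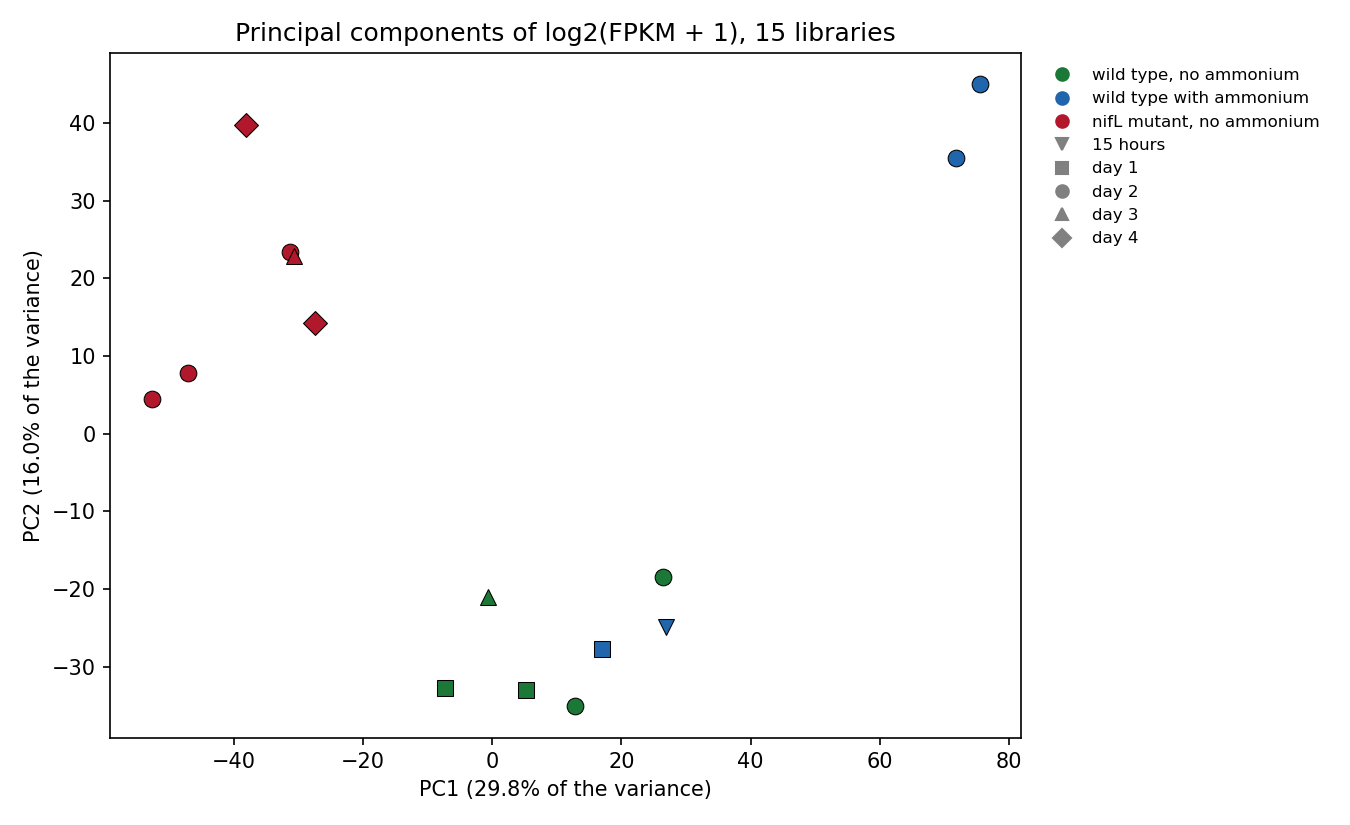
The first and second principal components of log2(FPKM + 1) over the 4872 tested genes, 1 point per library, with 29.8% and 16% of the variance on the axes (colour for strain and medium, symbol for time). The ammonium day 2 libraries lie at 75.5 and 71.8 on the first component and the mutant libraries between -52.7 and -27.5.

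In the mutant at day 2, the genes of molybdenum nitrogenase were far higher than in the wild type in the same medium (3 against 2 libraries, each mutant library above each wild-type one). nifH rose from 2754 to 86247 FPKM (log2 change 5.02, SE 0.50, adjusted p = 0.00146). nifD, for the alpha subunit of dinitrogenase, rose from 410 to 11122 FPKM (4.73, SE 0.55, adjusted p = 0.00261), and nifK, for its beta subunit, from 637 to 8046 FPKM (adjusted p = 0.00275). nifL rose 85.0-fold (log2 change 6.41, SE 0.24, adjusted p = 1.56e-05), while nifA was at 129 FPKM against 123 (0.11, SE 0.30, adjusted p = 0.823). Of the 32 genes of the major nif region, 30 rose and 0 fell (32 rose adjusted over the list alone). Examples are nifF, a flavodoxin that passes electrons to nitrogenase (11530 against 1110 FPKM, adjusted p = 6.35e-04), iscAnif (4728 against 268 FPKM), nifE (2363 against 227 FPKM) and the tag Avin_01500 (6595 against 675 FPKM). The median log2 change of that region was 3.00 (camera adjusted p = 6.86e-23, and adjusted p = 0.300 with an estimated correlation). Of the 21 genes with a nif symbol, 19 rose over all genes and adjusted over the list alone (median 3.27, camera adjusted p = 5.08e-14, and adjusted p = 0.300 with an estimated correlation). In the minor region around nifA, 14 of 17 genes rose and 1 fell, with the same counts adjusted over the list alone (median 2.95, camera adjusted p = 5.74e-09, and adjusted p = 0.300 with an estimated correlation). Its members include nifB, needed for the cofactor of nitrogenase (2021 against 170 FPKM), and nifO (1412 against 123 FPKM). The rnf genes, for a membrane complex that supplies electrons, rose in 7 of 13 cases (7 adjusted over the list alone, median 2.04, camera adjusted p = 2.01e-06, and adjusted p = 0.300 with an estimated correlation). These include rnfA1 (8.34-fold), rnfG1 and rnfE1, all within the minor nif region. Of the 6 rnf genes outside it 0 were called by limma (2 at an unadjusted p under 0.05). Against the wild type of day 1, chosen after the data were seen, 29 of 32 genes of the major region, 13 of 17 of the minor region and 7 of 13 rnf genes rose (30, 14 and 8 adjusted over the list alone).

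The alternative nitrogenases did not follow. anfH fell from 37.8 to 10.8 FPKM (log2 change -1.72, SE 0.32, adjusted p = 0.0153), and 4 of 8 anf genes fell and 0 rose (4 fell and 1 rose adjusted over the list alone), anfO and anfK among them. The median of the anf list was -0.89 (camera adjusted p = 0.0343, and adjusted p = 0.410 with an estimated correlation). vnfH stood at 45.0 against 54.7 FPKM (adjusted p = 0.648). In the vnf list, 1 of 13 genes fell, vnfA3 (log2 change -1.30, adjusted p = 0.0251), with 1 adjusted over the list alone and a median of -0.90 (camera adjusted p = 0.0172, and adjusted p = 0.508 with an estimated correlation). Of the ammonium assimilation genes 1 of 9 rose (0 adjusted over the list alone): glnA, for glutamine synthetase, from 527 to 2438 FPKM (2.21, SE 0.60, adjusted p = 0.0440). amtB, for an ammonium transporter, stood at 356 against 670 FPKM (adjusted p = 0.145). Among 20 hydrogenase genes 1 fell, hoxY (-1.96, adjusted p = 0.0453), and 0 adjusted over the list alone, with a list median of -0.34 (camera adjusted p = 0.0161, and adjusted p = 0.508 with an estimated correlation). Several of these calls depend on the day of the wild type. anfH stood at 10.7 and 14.9 FPKM in the wild type at day 1, 28.7 and 46.8 at day 2 and 16.7 at day 3, against 7.39 to 13.3 in the mutant at day 2. Against the wild type of day 1, chosen after the data were seen, the log2 change was -0.25 for anfH (adjusted p = 0.684), -0.71 for anfO (0.157), -0.21 for anfK (0.589), -0.73 for vnfA3 (0.215), -1.46 for hoxY (0.189) and 0.61 for glnA (0.599). Of the anf, vnf and hydrogenase lists 0 members were called there by limma (1, 2 and 3 at an unadjusted p under 0.05). Some rest on single libraries. glnA reached adjusted p = 0.302 and anfH 0.123 without wild-type day 2 replicate 1.

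Flagellar, ribosomal protein, amino acid and NADH dehydrogenase genes also lay higher in the mutant at day 2. Of 52 flagellar and chemotaxis genes 31 rose and 1 fell (33 and 1 adjusted over the list alone), with a median log2 change of 1.18 (camera adjusted p = 6.91e-13, and adjusted p = 0.300 with an estimated correlation). fliC, for flagellin, rose from 240 to 1825 FPKM (adjusted p = 7.97e-04), fliD, for the filament cap, from 55.3 to 302 FPKM, and cheB from 15.9 to 62.2 FPKM. Of 41 ribosomal protein genes 10 rose (12 adjusted over the list alone, median 0.92, camera adjusted p = 2.95e-08, and adjusted p = 0.410 with an estimated correlation). rplL stood at 2931 against 1018 FPKM. Of 77 amino acid biosynthesis genes 15 rose (15 adjusted over the list alone, median 0.38, camera adjusted p = 3.43e-04, and adjusted p = 0.300 with an estimated correlation). ilvC rose 3.27-fold, ilvI 2.32-fold and trpB 4.64-fold. NADH dehydrogenase genes rose in 4 of 20 cases (8 adjusted over the list alone, median 0.61, camera adjusted p = 1.31e-05, and adjusted p = 0.300 with an estimated correlation). nqrA rose 2.67-fold. Iron-sulfur cluster assembly genes rose in 5 of 12 cases (8 adjusted over the list alone, median 0.96, camera adjusted p = 4.03e-04, and adjusted p = 0.326 with an estimated correlation). Outside the nif regions 4 of 11 rose, since iscAnif lies in the major one. iscU stood at 563 against 279 FPKM. ATP synthase genes rose in 2 of 9 cases (6 adjusted over the list alone, median 0.91, camera adjusted p = 0.00215, and adjusted p = 0.410 with an estimated correlation). In the tricarboxylic acid cycle list 4 of 19 genes rose and 1 fell (9 and 1 adjusted over the list alone, median 0.77, camera adjusted p = 0.00619, and adjusted p = 0.441 with an estimated correlation). fumC1, a fumarase gene, stood at 336 against 52.8 FPKM. Oxidative stress genes rose in 3 of 8 cases, trxA among them (4 rose and 1 fell adjusted over the list alone, median 0.70, camera adjusted p = 0.0283, and adjusted p = 0.300 with an estimated correlation). For translation factors and tRNA synthetases 1 of 26 rose, tsf (0 adjusted over the list alone, median 0.30, camera adjusted p = 0.0269, and adjusted p = 0.534 with an estimated correlation). With the libraries rescaled to equal sums, the medians of the NADH dehydrogenase (-0.22), tricarboxylic acid cycle (-0.07), translation factor (-0.54), oxidative stress (-0.14) and amino acid (-0.45) lists turned negative, since that scaling moved the median of all genes to -0.83. Relative to the median of all genes, these lists kept their direction under each scaling. Against the wild type of day 1, chosen after the data were seen, 25 of 52 flagellar genes and 5 of 77 amino acid genes rose (43 and 5 adjusted over the list alone). Of the ribosomal protein, NADH dehydrogenase and ATP synthase genes 0 were called there by limma (8, 1 and 0 at an unadjusted p under 0.05), with medians of 0.41, 0.26 and 0.21. Of 12 iron-sulfur cluster assembly genes 1 rose (3 adjusted over the list alone, median 0.68), and of 19 tricarboxylic acid cycle genes 2 rose (5 adjusted over the list alone, median 0.64). Of the oxidative stress and translation genes 0 were called by limma (3 and 3 at an unadjusted p under 0.05), with medians of 0.12 and 0.12. There rplL was at 1.02 (adjusted p = 0.0609), iscU at 0.62 (0.176), nqrA at 0.34 (0.512), tsf at 0.51 (0.276) and trxA at 0.46 (0.259).

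**Figure D3:**
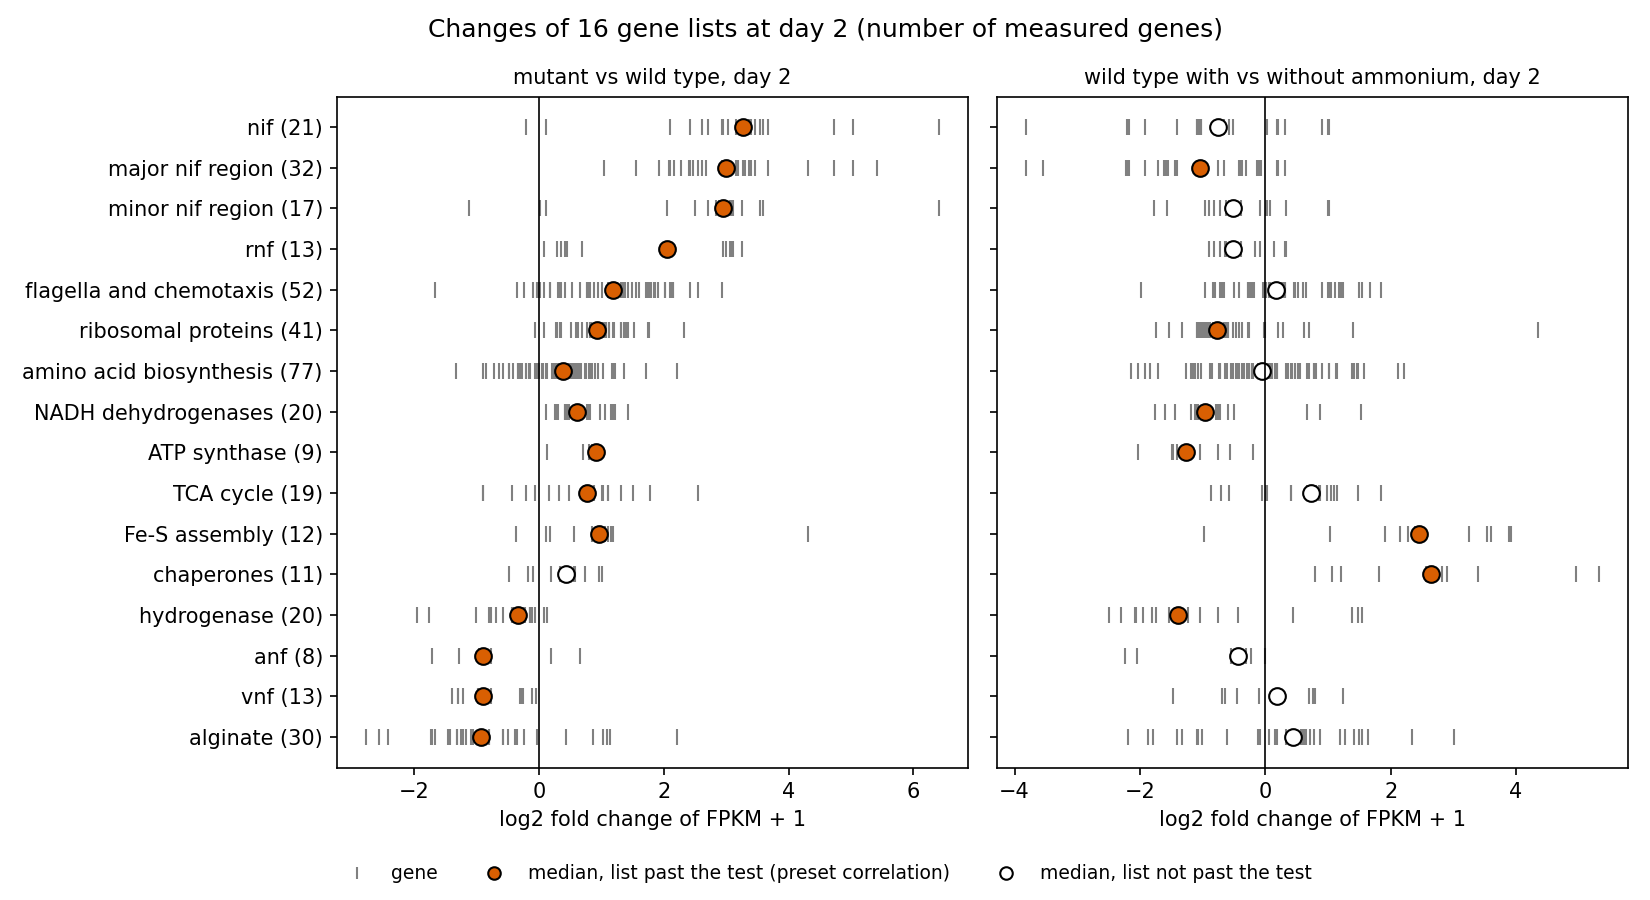
Log2 change of FPKM + 1 at day 2 for the genes of 16 lists (ticks) and their medians (circles, filled where the list passed camera at the preset correlation), for mutant against wild type (left) and wild type with against without ammonium (right). The median of the major nif region lies at 3.00 and -1.04, and that of iron-sulfur cluster assembly at 0.96 and 2.44.

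The largest falls among genes with a symbol in the mutant at day 2 were pdhA (900 to 70.9 FPKM, log2 change -3.75, adjusted p = 0.0122) and pdhB (444 to 38.0 FPKM), which encode parts of pyruvate dehydrogenase, then mdcC (91.7 to 7.56 FPKM), mdcG and mdcD, of malonate decarboxylase, citG, scrT and wbpP. Of 30 alginate genes 7 fell and 4 rose (15 and 5 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 0.0145, and adjusted p = 0.410 with an estimated correlation). algD, for an enzyme that makes the alginate precursor, fell from 716 to 108 FPKM, while algE7 rose from 173 to 824 FPKM. Of 5 genes for cyst lipids and rpoS, 1 fell (5 adjusted over the list alone, median -2.84, camera adjusted p = 0.0143, and adjusted p = 0.410 with an estimated correlation): rpoS, for a stationary-phase sigma factor, at 2017 against 4227 FPKM (adjusted p = 0.0475). arsD stood at 231 against 1167 FPKM (adjusted p = 0.0732). In the wild type arsD was at 154 FPKM at day 1. Against the wild type of day 1, chosen after the data were seen, the cyst list had a median of 0.087, with 0 of 5 and 0 of 30 alginate genes called by limma (0 and 6 at an unadjusted p under 0.05). The log2 change was -0.39 for rpoS there (adjusted p = 0.497), -2.01 for pdhA (0.137), -1.95 for pdhB (0.165), -0.99 for algD (0.401), -0.80 for mdcC (0.483), -0.59 for mdcG (0.564) and 0.40 for mdcD (0.621). citG (-0.12), scrT (-1.75), wbpP (-1.01) and algE7 (1.35) were not called there either. Without wild-type day 2 replicate 1, algD reached adjusted p = 0.199 and pdhA 0.117. The tags Avin_25630 (14985 against 83.1 FPKM) and Avin_25620 (2825 against 32.4 FPKM) had the largest rises without a value of 0.

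In all, 352 genes rose and 459 fell between mutant and wild type at day 2 (limma, 43.4% higher), and at an unadjusted p under 0.05 there were 1680. With the wild type of day 1 in place of day 2, chosen after the data were seen, 153 rose and 39 fell. Libraries rescaled to equal sums gave 99 higher and 1681 lower (5.56% higher), and equal sums outside the high-numbered tags gave 181 and 820 (18.1%, median of all genes -0.29). The count rests on single libraries: it was 98 without wild-type day 2 replicate 1, 538 without replicate 2, and 162 and 214 without mutant day 2 replicates 1 and 2. Of 53 named genes that were called, 14 kept the call with each library left out, and these were cheB, fliC, fliD, ilvI, iscAnif, mdcD, nifD, nifF, nifH, nifK, nifL, rnfA1, rnfE1 and rnfG1. The calls lost numbered 39 without wild-type day 2 replicate 1, 18 without replicate 2, and 31, 23 and 2 without mutant day 2 replicates 1, 2 and 3. With the series of library names as a block 861 genes were called, and within the largest name series (2 mutant libraries and 1 of the wild type, with 2 residual degrees of freedom from mutant libraries alone) 26 were, with nifL at 6.50 (adjusted p = 0.00531) and nifH at 5.59 (adjusted p = 0.135).

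Several lists gave no result past the list test (camera) in this comparison, and those tested had a fry adjusted p of 0.0594 or above. Of the lists past camera, vnf (fry adjusted p = 0.104), hydrogenase (0.110) and translation (0.212) did not pass fry. Members called were 0 of 16 for molybdenum, 0 of 11 for nitrate and urea, and 0 of 11 for chaperones by limma, also adjusted over the list alone (1, 1 and 2 at an unadjusted p under 0.05). They were 3 that fell of 14 for terminal oxidases (3 rose and 3 fell adjusted over the list alone), 1 that fell of 7 for polyhydroxybutyrate (1 adjusted over the list alone), and 3 that rose and 2 that fell of 23 for iron uptake (3 and 4 adjusted over the list alone). The camera adjusted p lay between 0.138 (terminal oxidases) and 0.656 (molybdenum). The 4 fix genes had 0 calls (0 at an unadjusted p under 0.05) and a median of 0.67, and the gas vesicle list had 0 genes in the table. The medians of the molybdenum, ammonium assimilation, nitrate and urea, and iron lists changed sign with the scaling.

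With ammonium at day 2, nitrogenase genes of the wild type were lower, and genes of heat shock and iron-sulfur cluster assembly were higher (2 against 2 libraries, without overlap between groups for each gene called). nifH fell from 2754 to 194 FPKM (log2 change -3.82, SE 0.55, adjusted p = 0.00218), nifD from 410 to 90.9 FPKM (-2.18, SE 0.60, adjusted p = 0.0259), nifK from 637 to 165 FPKM (adjusted p = 0.0165) and nifF from 1110 to 244 FPKM (adjusted p = 0.00183). The regulators went the other way: nifL rose from 49.0 to 103 FPKM (1.02, adjusted p = 0.0190) and nifA from 123 to 243 FPKM (1.00, adjusted p = 0.0459). Of the major nif region 11 of 32 genes fell and 0 rose, with the same counts adjusted over the list alone (median -1.04, camera adjusted p = 8.13e-04, and adjusted p = 0.884 with an estimated correlation). Of the nif genes 3 of 21 rose and 4 fell, also adjusted over the list alone (median -0.75, camera adjusted p = 0.271). anfH fell from 37.8 to 7.0 FPKM (adjusted p = 0.00292), and 2 of 8 anf genes fell (2 adjusted over the list alone, camera adjusted p = 0.105). glnA stood at 238 against 527 FPKM (adjusted p = 0.179), amtB at 435 against 670 FPKM (adjusted p = 0.233), vnfH at 99.8 against 54.7 FPKM (adjusted p = 0.189) and nifB at 140 against 170 FPKM (adjusted p = 0.576). The calls of nifL, nifA, nifD and nifK ended when single libraries were left out, as with nifK at 0.0898 without wild-type day 2 replicate 1 and 0.0735 without ammonium day 2 replicate 2.

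With ammonium the small heat-shock genes ibpB (403 to 22030 FPKM, log2 change 5.32, adjusted p = 0.00326) and ibpA (595 to 22929 FPKM) rose, as did lon, for a protease (68.4 to 1900 FPKM), fdhD, for a protein that matures formate dehydrogenase (46.9-fold, adjusted p = 2.01e-04), hepA, phhB and hutH, for histidine breakdown (16.3-fold). Of 11 chaperone genes 7 rose and 0 fell (9 adjusted over the list alone, median 2.64, camera adjusted p = 2.54e-04, and adjusted p = 0.884 with an estimated correlation). Of 12 genes of iron-sulfur cluster assembly 10 rose and 0 fell (11 adjusted over the list alone, median 2.44, camera adjusted p = 3.74e-07, and adjusted p = 0.857 with an estimated correlation). iscS stood at 3260 against 217 FPKM, iscA at 3432 against 230 FPKM (adjusted p = 1.21e-04), iscU at 3367 against 279 FPKM and hscB at 9.55-fold. Lower with ammonium were oprG-1 (221 to 9.96 FPKM, log2 change -4.53, adjusted p = 0.00117), pilA, for type IV pilin (2413 to 276 FPKM), ssuE, scrT, fucP, alyA3 and greB. Of 20 hydrogenase genes 14 fell and 1 rose (14 and 3 adjusted over the list alone, median -1.40, camera adjusted p = 2.54e-04, and adjusted p = 0.884 with an estimated correlation). hypE fell from 74.6 to 20.6 FPKM and hoxK from 266 to 92.9 FPKM. NADH dehydrogenase genes fell in 11 of 20 cases (15 fell and 2 rose adjusted over the list alone, median -0.96, camera adjusted p = 0.00104, and adjusted p = 0.884 with an estimated correlation). nuoG was 2.70-fold lower. ATP synthase genes fell in 6 of 9 cases (7 adjusted over the list alone, median -1.26, camera adjusted p = 0.00558, and adjusted p = 0.884 with an estimated correlation). atpI stood at 87.4 against 359 FPKM. Ribosomal protein genes fell in 4 of 41 cases and rose in 1 (0 fell and 1 rose adjusted over the list alone, median -0.77, camera adjusted p = 0.0192, and adjusted p = 0.884 with an estimated correlation). rplM stood at 648 against 1986 FPKM and rplL at 2676 against 1018 FPKM. The tags Avin_25880 (959 against 7.91 FPKM) and Avin_18300 (1486 against 26443 FPKM) had the largest rise and fall among tags without a value of 0 on either side.

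These differences at day 2 were not all present earlier. When the ammonium libraries of 15 hours and day 1 were set against the wild type of day 1, an alternative chosen after the data were seen, 9 genes were called against 1588 at day 2. nifH was again lower (log2 change -5.64, adjusted p = 0.00856), with medians of -1.37 for the major nif region, 0.06 for iron-sulfur cluster assembly and 0.25 for chaperones. Of the major nif region 2 of 32 genes fell (16 adjusted over the list alone, camera adjusted p = 1.64e-23, and adjusted p = 0.482 with an estimated correlation). Of 21 nif genes 1 fell (10 adjusted over the list alone), and their median of -1.68 lay further from 0 than at day 2 (camera adjusted p = 7.44e-14, and adjusted p = 0.482 with an estimated correlation). The minor region had a median of -1.23 (camera adjusted p = 7.18e-08, and adjusted p = 0.482 with an estimated correlation) and the rnf genes one of -0.43 (camera adjusted p = 2.02e-04, and adjusted p = 0.482 with an estimated correlation). Of these 2 lists 0 members were called by limma (9 and 6 at an unadjusted p under 0.05), and 7 and 6 fell adjusted over the list alone. Of the iron-sulfur, chaperone, hydrogenase, NADH dehydrogenase, ATP synthase and ribosomal protein genes 0 were called by limma (1, 0, 5, 6, 3 and 0 at an unadjusted p under 0.05). Adjusted over the list alone, 1 iron-sulfur and 1 ATP synthase gene fell. The medians were -0.53 for hydrogenase genes (camera adjusted p = 2.30e-04, and adjusted p = 0.565 with an estimated correlation) and -0.74 for ATP synthase genes (camera adjusted p = 2.35e-05, and adjusted p = 0.482 with an estimated correlation). They were -0.11 for NADH dehydrogenase genes (camera adjusted p = 0.0312, and adjusted p = 0.615 with an estimated correlation) and -0.028 for ribosomal protein genes (camera adjusted p = 0.746, and adjusted p = 0.993 with an estimated correlation). nifL was at -0.37 (limma adjusted p = 0.72) and nifA at -0.35 (0.785) in that comparison. Their sign was opposite to day 2, but neither was called, and anfH was at -0.45 (adjusted p = 0.750).

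In all, 809 genes rose and 779 fell with ammonium at day 2 (limma, 50.9% higher), and 2165 had an unadjusted p under 0.05. The split was 978 and 586 after median centring (62.5% higher), 373 and 1048 with equal sums (26.3%, median of all genes -0.63) and 347 and 2323 with equal sums outside the high-numbered tags (13.0%, median -0.98). The count was 938 without wild-type day 2 replicate 2, and of 38 named genes called 26 kept the call with each library left out. The others were nifL, nifA, nifD, nifK, alyA3, atpG, fucP, pilA, rplM, rpsG, scrT and ssuE, with 9 calls lost without either wild-type day 2 replicate and 5 and 8 without ammonium day 2 replicates 1 and 2. With the name series as a block 1495 genes were called, within the largest name series (1 library against 1, with the spread of mutant libraries) 495, and with only the compared libraries in the fit 37.

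Other lists did not pass the list test (camera) with ammonium at day 2. By fry, however, the nitrate and urea (adjusted p = 0.00707) and anf (0.0265) lists passed. Of the lists past camera, the major nif region (fry adjusted p = 0.0834) and ribosomal proteins (0.328) did not pass fry. Counts that rose and fell were 12 and 2 of 52 flagellar genes, 16 and 15 of 77 amino acid genes, 2 and 10 of 26 translation genes, 3 and 0 of 19 tricarboxylic acid cycle genes, 5 and 5 of 30 alginate genes, 4 and 1 of 16 molybdenum genes, 4 and 1 of 14 terminal oxidase genes, 2 and 3 of 23 iron genes, and 0 and 3 of 11 nitrate and urea genes. Adjusted over the list alone these were 12 and 2, 16 and 18, 2 and 10, 2 and 0, 6 and 5, 4 and 1, 4 and 1, 2 and 3, and 2 and 3. In the minor nif region 2 rose and 1 fell of 17 (1 and 1 adjusted over the list alone), and the other lists had at most 2 calls. The 4 fix genes had 0 calls by limma (3 at an unadjusted p under 0.05) and a median of -1.77. The medians of the vnf, molybdenum, terminal oxidase, alginate, flagellar and tricarboxylic acid cycle lists changed sign with the scaling.

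Set against the wild type with ammonium, the mutant at day 2 showed the widest differences (3 against 2 libraries). nifH was 459-fold higher (86247 against 194 FPKM, log2 change 8.84, SE 0.50, adjusted p = 2.91e-05), nifD 6.91 and nifK 5.59 higher on the log2 scale, nifF 47.8-fold and iscAnif 39.3-fold. nifL was 42.0-fold higher (adjusted p = 9.98e-06), and glnA by 3.46 on the log2 scale (2438 against 238 FPKM, adjusted p = 0.00213). nifA was lower, at 129 against 243 FPKM (-0.89, SE 0.30, adjusted p = 0.0346), a call that ended without any 1 of the 5 libraries (adjusted p from 0.0555 to 0.175). anfH (10.8 against 7.0 FPKM, adjusted p = 0.202), vnfH (adjusted p = 0.0501) and amtB (adjusted p = 0.720) were not called. The major nif region rose in 32 of 32 cases, also adjusted over the list alone (median 4.03, camera adjusted p = 1.85e-14, and adjusted p = 0.502 with an estimated correlation). Genes with a nif symbol rose in 19 of 21 and fell in 2, also adjusted over the list alone (median 4.13, camera adjusted p = 3.05e-07, and adjusted p = 0.502 with an estimated correlation). The minor region rose in 16 of 17 and fell in 1, also adjusted over the list alone (median 3.34, camera adjusted p = 4.15e-06, and adjusted p = 0.502 with an estimated correlation). The rnf genes rose in 10 of 13 (11 adjusted over the list alone, median 2.74, camera adjusted p = 1.74e-04, and adjusted p = 0.502 with an estimated correlation).

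In the same comparison, ribosomal protein genes rose in 30 of 41 cases (31 adjusted over the list alone, median 1.66, camera adjusted p = 5.54e-07, and adjusted p = 0.551 with an estimated correlation). rpmA stood at 1280 against 300.4 FPKM. NADH dehydrogenase genes rose in 17 of 20 (17 adjusted over the list alone, median 1.64, camera adjusted p = 4.93e-06, and adjusted p = 0.502 with an estimated correlation), and nqrA 5.66-fold. ATP synthase genes rose in 8 of 9 (9 adjusted over the list alone, median 2.15, camera adjusted p = 2.07e-04, and adjusted p = 0.502 with an estimated correlation), and atpB 4.75-fold. Flagellar genes rose in 28 of 52 and fell in 4 (28 and 4 adjusted over the list alone, median 0.87, camera adjusted p = 2.07e-04, and adjusted p = 0.551 with an estimated correlation). Hydrogenase genes rose in 12 of 20 and fell in 4 (13 and 4 adjusted over the list alone, median 1.05, camera adjusted p = 0.0166, and adjusted p = 0.598 with an estimated correlation). Translation genes rose in 14 of 26 and fell in 1 (15 and 3 adjusted over the list alone, median 0.82, camera adjusted p = 0.00424, and adjusted p = 0.586 with an estimated correlation). Amino acid genes rose in 32 of 77 and fell in 14 (32 and 14 adjusted over the list alone, median 0.46, camera adjusted p = 0.0245, and adjusted p = 0.502 with an estimated correlation). Iron-sulfur cluster assembly genes fell in 10 of 12 cases and rose in 1 (10 and 1 adjusted over the list alone, median -2.35, camera adjusted p = 3.89e-04, and adjusted p = 0.502 with an estimated correlation). Chaperone genes fell in 7 of 11 (8 adjusted over the list alone, median -2.22, camera adjusted p = 0.00601, and adjusted p = 0.598 with an estimated correlation). ibpB stood at 314 against 22030 FPKM. mdcG (4.56 against 296 FPKM), hutU (173 against 5271 FPKM), gcd (58.7 against 2059 FPKM), fdhD, hutI, citG and mdcC also fell, while oprG-1 rose 73.8-fold. The other lists did not pass the list test (camera adjusted p = 0.0671 or above), with 8 alginate genes of 30 higher and 16 lower (9 and 17 adjusted over the list alone) and 3 of 4 fix genes higher. Of these, the nitrate and urea (adjusted p = 5.28e-04), molybdenum (0.0281) and vnf (0.04998) lists did pass fry.

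In all, 1219 genes rose and 1251 fell in the mutant against the wild type with ammonium (limma, 49.4% higher), 2772 had an unadjusted p under 0.05, and 2440 were called with the name series as a block. With equal sums 541 rose and 1202 fell (31.0% higher, median of all genes -0.17), and with equal sums outside the high-numbered tags 1998 rose and 717 fell (73.6%, median 0.70). Of 48 named genes called 47 kept the call with each library left out. Against the ammonium libraries of 15 hours and day 1, chosen after the data were seen, 755 genes were called. There 31 of 32 genes of the major nif region and 32 of 52 flagellar genes rose (31 and 42 adjusted over the list alone). Other lists differed from day 2. Iron-sulfur cluster assembly genes rose in 2 of 12 cases (2 rose and 1 fell adjusted over the list alone) with a median of 0.47 in place of -2.35, the other direction. Chaperones had a median of 0.094 in place of -2.22, and 0 of 11 were called by limma, also adjusted over the list alone (1 at an unadjusted p under 0.05). Ribosomal protein genes rose in 2 of 41 cases (0 adjusted over the list alone, median 0.48), and NADH dehydrogenase genes in 4 of 20 (6 adjusted over the list alone, median 0.42). ATP synthase genes rose in 4 of 9 (6 adjusted over the list alone, median 0.99). Translation, hydrogenase and amino acid genes no longer passed the list test. Of 26 translation genes 0 were called by limma, also adjusted over the list alone (3 at an unadjusted p under 0.05, median 0.15, camera adjusted p = 0.515, and adjusted p = 0.826 with an estimated correlation). Of 20 hydrogenase genes 4 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.27, camera adjusted p = 0.364, and adjusted p = 0.745 with an estimated correlation). Of 77 amino acid genes 10 rose (7 adjusted over the list alone, median 0.15, camera adjusted p = 0.182, and adjusted p = 0.647 with an estimated correlation).

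The changes of the wild type without ammonium and of the mutant, each against the wild type with ammonium at day 2, correlated across genes at 0.703 (genes are not independent replicates). Both use the same 2 ammonium libraries. Simulated groups without any change, against the same controls, gave a mean correlation of 0.544 and at most 0.635. Each gene was drawn on its own in these simulations, so their spread may be too narrow for correlated genes. The covariance was 1.75 against a simulated mean of 0.27 and maximum of 0.36, leaving 1.48. With a separate ammonium library as control for each comparison, chosen after the data were seen, the correlation was 0.484 or 0.476 and the covariance 1.39 or 1.37. Of 779 genes higher without ammonium and 1219 higher in the mutant, 581 were in both, where independent lists would share 195 (the product of both counts over the 4872 genes). Of 809 and 1251 lower genes 713 were in both (208 if independent), and 8 were called in opposite directions. Independent lists are no baseline here, since the controls are shared, and part of the excess may come from them. In simulations chosen after the data were seen, with the same controls and no change, at most 1 gene was called in both in either direction. These sets had at most 2 genes called in any comparison and direction, so they cannot show how much overlap shared controls give. With changes dealt to genes at random for each comparison, on average 123 were higher in both (at most 145) and 148 lower (at most 170). These changes were put into the wild type without ammonium and the mutant, and none into the ammonium group. A change of the ammonium cultures themselves at day 2 would enter both comparisons, also with separate ammonium libraries. The overlap therefore cannot part such a change from one shared by the mutant and the wild type without ammonium. With separate controls 309 or 385 genes were higher in both (115 or 131 if independent) and 582 or 483 lower (162 or 146).

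Over all times, where the arms also differ in the times sampled, the nitrogenase genes gave the same directions. Against the wild type without ammonium (6 against 5 libraries), the mutant had nifH at 78509 against 3099 FPKM (log2 change 4.63, SE 0.37, adjusted p = 1.20e-06), nifK at 11.8-fold, nifL at 4874 against 57.8 FPKM (82.4-fold, adjusted p = 6.99e-10), and nifD, iscAnif and nifE higher. holA (398 to 86.2 FPKM), scrT, pdhA, pdhB and tctC, for a tricarboxylate-binding protein, fell. pdhA lost its call without wild-type day 2 replicate 2 (adjusted p = 0.0534), and pdhB without replicate 1 (0.0553) and replicate 2 (0.0608). In all, 380 genes rose and 271 fell (limma, 58.4% higher, 1422 at an unadjusted p under 0.05). With equal sums 95 rose and 3704 fell (2.50%, median of all genes -1.28), and with equal sums outside the high-numbered tags 196 and 866 (18.5%, median -0.40). The count was 386 without wild-type day 2 replicate 2 and 426 without replicate 1, 827 with the name series as a block and 71 within the largest name series.

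With ammonium over all times (4 against 5 libraries) nifH fell from 3099 to 134 FPKM (log2 change -4.67, SE 0.41, adjusted p = 5.12e-05), nifD from 523 to 65.6 FPKM (adjusted p = 0.00257) and nifK by 1.95 on the log2 scale. fixC, of an electron transfer system (367 to 46.6 FPKM), fixX and oprG-1 fell, and sdaA, for a serine deaminase (59.1 to 518 FPKM), kdpD, kdpE, gcd and gcvT3 rose. In all, 119 genes rose and 148 fell (limma, 44.6% higher, 1517 at an unadjusted p under 0.05). The split was 257 and 136 after median centring (65.4% higher), 28 and 72 with equal sums (28.0%, median of all genes -0.38) and 71 and 524 with equal sums outside the high-numbered tags (11.9%, median -0.55). The count was 18 without ammonium day 2 replicate 2, 53 without replicate 1, 822 without the ammonium library of 15 hours and 1209 without that of day 1. Of 11 named genes called, nifH, nifD and nifK kept the call with each library left out. With the name series as a block 432 genes were called, and 4 within the largest name series.

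The mutant against the wild type with ammonium over all times (6 against 4 libraries) had nifH 629-fold higher (log2 change 9.30, SE 0.39, adjusted p = 1.63e-09), with nifD, nifK, iscAnif and nifL higher, and pdhB (44.7 against 614 FPKM), gcd, hutU, hutI and pdhA lower. All 10 named genes called kept the call with each library left out. In all, 821 genes rose and 853 fell (limma, 49.0% higher, 2243 at an unadjusted p under 0.05), 1658 with the name series as a block and 537 within the largest name series. With equal sums 125 rose and 2265 fell (5.23% higher, median of all genes -0.86).

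Few genes were called between times in the mutant and in the wild type without ammonium. In the mutant, day 4 against day 2 (2 against 3 libraries) gave 4 calls by limma, all locus tags (640 at an unadjusted p under 0.05): Avin_25880 (21.4 against 7.09 FPKM) and Avin_18750 rose, and Avin_44090 (22.9 against 103 FPKM) and Avin_37660 (listed at 0 at day 4) fell. With the name series as a block 139 genes were called, 17 higher and 122 lower. The count was 26 without mutant day 2 replicate 3, 15 without mutant day 4 replicate 1 and 2 without mutant day 2 replicate 2. nifL stood at 6077 against 4263 FPKM (adjusted p = 0.408), nifH at 77190 against 86247 FPKM (adjusted p = 0.842) and glnA at 1382 against 2438 FPKM (adjusted p = 0.675). Of 52 flagellar genes 0 were called by limma, also adjusted over the list alone (12 at an unadjusted p under 0.05), with a median of -0.46 (camera adjusted p = 1.83e-07, and adjusted p = 0.976 with an estimated correlation) and fliC at 930.4 against 1825 FPKM (adjusted p = 0.155). Of 20 NADH dehydrogenase genes 0 were called by limma (3 rose adjusted over the list alone, and 7 had an unadjusted p under 0.05), with a median of 0.45 (camera adjusted p = 0.00777, and adjusted p = 0.976 with an estimated correlation).

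In the wild type without ammonium, day 2 against day 1 (2 against 2 libraries) gave 5 calls by limma, all locus tags (547 at an unadjusted p under 0.05). Avin_18750 (34.5 against 0.64 FPKM) and Avin_39900 (73.1 against 29.1 FPKM) rose, and the 3 that fell were listed at 0 at day 2. The count was 1 with the name series as a block, 24 without wild-type day 2 replicate 2 and 11 without wild-type day 1 replicate 1. The cyst lipid genes had the largest median, 2.91 (0 of 5 called by limma, also adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.00308, and adjusted p = 0.555 with an estimated correlation). arsD stood at 1167 against 154 FPKM (adjusted p = 0.352). Ribosomal protein genes had a median of -0.52 (0 of 41 called by limma, also adjusted over the list alone, 5 at an unadjusted p under 0.05, camera adjusted p = 6.10e-06, and adjusted p = 0.732 with an estimated correlation). The other lists past the list test, each with 0 members called over all genes, had medians of 0.64 (anf), 0.31 (flagella), -0.62 (ATP synthase), -0.35 (NADH dehydrogenase), -0.62 (oxidative stress), -0.20 (translation) and -0.09 (amino acids). At an unadjusted p under 0.05 there were 5 of 8, 9 of 52, 1 of 9, 5 of 20, 4 of 8, 2 of 26 and 3 of 77 members by limma, in that order. Adjusted over the list alone 3 anf genes and 1 flagellar gene rose, and 1 ATP synthase and 1 oxidative stress gene fell. Their adjusted p with an estimated correlation lay at 0.555 or above.

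The change from day 1 to day 2 differed between the media for 258 genes by limma (174 higher and 84 lower with ammonium, 1220 at an unadjusted p under 0.05). The test rests on 1 ammonium library at day 1. With that of 15 hours in its place, chosen after the data were seen, 71 genes were called, 67 of them among the 258 in the same direction. Iron-sulfur cluster assembly genes made up 8 of them, out of 12 (10 adjusted over the list alone, median 2.25, camera adjusted p = 3.28e-09, and adjusted p = 0.530 with an estimated correlation). Chaperones had a median of 2.12 (0 of 11 called by limma, 3 adjusted over the list alone and 4 at an unadjusted p under 0.05, camera adjusted p = 0.00505, and adjusted p = 0.829 with an estimated correlation). Hydrogenases had a median of -0.89 (1 of 20 lower, 2 adjusted over the list alone, camera adjusted p = 0.00505, and adjusted p = 0.829 with an estimated correlation). Other lists past the list test had medians of 0.88 (nif), -0.78 (NADH dehydrogenase), -0.96 (ribosomal proteins), -0.68 (translation) and 0.44 (flagella), each at adjusted p = 0.829 with an estimated correlation. The count was 19 without wild-type day 1 replicate 2, 40 with the name series as a block, 49 with equal sums (median of all genes -0.35) and 766 with equal sums outside the high-numbered tags (100 higher and 666 lower, 13.1%, median -0.80).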

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

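The tests of explanations for the 2 patterns weighed here were chosen after the result was seen, while quantile normalization, libraries left out, the name series as a block and the difference between media were planned.

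In the wild type, the change from day 1 to day 2 differed between cultures with and without ammonium for 258 genes, and for anfH by -2.36 on the log2 scale, by a test of the difference itself, which rests on 1 ammonium library at day 1. The genes always named were also tested for a value far from the others of an arm, in 30 combinations of gene and arm (0 outliers). The arms hold 4 to 6 libraries of mixed times, where 2 extreme libraries can mask each other. The test therefore says nothing on whole libraries.

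More genes were called between wild type with and without ammonium at day 2 (1588) than with the ammonium libraries of 15 hours and day 1 (9). Scaling alone is argued against by 1501 genes called after quantile normalization, and 1 odd library by 1238 genes without ammonium day 2 replicate 1 and 1303 without replicate 2. The series of library names stays open: as a block it left 1495 genes at day 2 against 3 early, but 73 against 16 without ammonium day 2 replicate 1. Time in culture with the same effect in both media would cancel between the media at day 2, which holds by design whatever the values. With ammonium, day 2 differed from the mean of 15 hours and day 1 by 858 genes higher and 719 lower (limma). Without ammonium, day 2 differed from day 1 by 2 higher and 3 lower. The test of the difference between the media called 258 genes, but 71 with ammonium at 15 hours in place of day 1. It called 40 with the name block and 49 with equal sums, but more with library weights and with equal sums outside the high-numbered tags. With 1 library left out the count was lower or higher, depending on the library. The size of that difference is therefore uncertain, and the test does not decide on time in culture. A state of the ammonium culture at day 2, such as its growth stage, may be the source and stays open and untested, as do differences between single cultures.

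nifL was higher in the mutant at day 2 while nifA, the next gene, was not called (95% interval of its log2 change up to 0.79). Scaling of the libraries is argued against by the log2 distance from nifA to nifL, at least 4.84 in each mutant library and between -1.61 and -0.76 in the others. A promoter in the insertion, transcripts that end before nifA, or reads of inserted sequence counted as nifL could each give this pattern and were not tested.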

How the results depend on the processing

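Alternatives with the early ammonium or wild-type day 1 libraries, with genes above 0 in every library, or with the high-numbered tags treated apart were chosen after the data were seen. Over named genes, 3388 values kept direction and side of the threshold, 490 lost a call, 16 gained one and 36 reversed. The causes were not tested, except that fits with fewer libraries have less power. Libraries left out were those of the groups or arms compared. No paired analysis was possible because replicate numbers are only the order of the samples. The depth is unknown, so its limit on low genes was not measured.

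Counts of genes that moved by over 1.5 times were as follows. Mutant against wild type at day 2 (811): 1780 with equal sums, 1458 with library weights, 296 with the compared groups only, 26 within AV.RNAn, 192 against wild type at day 1. Ammonium at day 2 (1588): 37 with the compared groups only, 495 within AV.RNAn, 686 for the mean of days, 2670 with equal sums outside the high-numbered tags, 9 with 15 hours and day 1. Mutant against ammonium at day 2 (2470): 755 with 15 hours and day 1. Day 4 against day 2 (4): 1 with pseudocount 0.1, 0 with pseudocount 10 (limma, 630 at an unadjusted p under 0.05), 1 with a filter of 20, 1 with equal sums, 2 without trend, 7 with weights, 139 with the name block, 1 outside the tags. Wild type day 2 against day 1 (5): 1 with a filter of 20, 8 median-centred, 3 with equal sums, 18 with weights, 1 with the name block, 1 with genes above 0. Difference between media (258): 71 with 15 hours for day 1, 131 quantile, 49 equal sums, 765 weights, 40 name block, 766 outside the tags. Over all times, mutant against wild type (651): 3799 equal sums, 1479 weights, 1062 outside the tags. Ammonium over all times (267): 100 equal sums, 997 weights, 432 name block, 1588 day 2 alone, 595 outside the tags.

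Lists past the test (18, 7, 13, 2, 9 and 8) numbered 0 by camera with an estimated correlation in each comparison, and 0, 0 and 1 with fry in the last 3. Of the 18, 10 passed against wild type at day 1. The correlation of 0.703 was 0.798 with genes above 0, 0.655 quantile-normalized, 0.732 to 0.747 with an ammonium library left out, and 0.484 and 0.476 with separate controls.

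With 1 library left out, counts ran from 98 to 1060 (mutant against wild type, day 2), 938 to 1303 (ammonium, day 2), 2054 to 2474 (mutant against ammonium, day 2), 2 to 26 (day 4 against day 2), 6 to 24 (wild type over time), 19 to 344 (difference between media), 386 to 691, 18 to 1209 and 1204 to 1965 (the 3 comparisons over all times).

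Log2 changes that reversed were these. Equal sums: nifA -0.72 and atpH -0.041 (mutant against wild type, day 2), nifL -0.012 (day 4 against day 2). Outside the tags: nifA -0.17, vnfH -0.17 (ammonium), amtB 0.48 (mutant against ammonium). Quantile: amtB 0.21. Name block: nifB 0.018 (ammonium). Within AV.RNAn: nifB 0.72 and amtB 0.14 (ammonium). With 1 library left out: nifA -0.23 to 0.45 (mutant against wild type), nifH -1.10 to 0.42 (day 4), nifB -1.59 to 0.44 (ammonium), amtB -0.74 to 0.37 (mutant against ammonium). With 15 hours and day 1, ammonium: nifL -0.37, nifA -0.35, fucP 0.34, alyA3 0.87, greB 0.47, iscA -0.080, hscB -0.14, nuoK 0.25, nuoJ 0.085, rplM 0.14. Mutant against these: nifA 0.54, mdcG 0.28, fdhD 0.34, hypE -0.15, hypD -0.10, iscA 0.43, iscU 0.60, hscB 0.27, serS -0.18, metJ -0.28. Against wild type at day 1: vnfH 0.029, mdcD 0.40.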

Other observations

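The tests of gene families in the first paragraph, and the comparison among ammonium libraries with its genes, were chosen after the data were seen. The test of the hypothesis and the splits of the samples were chosen before. Families were 80 sets of genes that share the first letters of a symbol, outside the fixed lists. With ammonium at day 2, all 5 hut genes for histidine breakdown rose in the wild type (median log2 change 3.06, camera adjusted p = 0.00783, and adjusted p = 0.746 with an estimated correlation). All 5 fdh genes, of formate dehydrogenase, rose (median 2.83, camera adjusted p = 0.00554, and adjusted p = 0.746 with an estimated correlation), as did all 5 pqq genes, for the cofactor pyrroloquinoline quinone (median 3.05, camera adjusted p = 0.00783, and adjusted p = 0.746 with an estimated correlation). With the earlier ammonium libraries against the wild type of day 1, hutH (log2 change 0.34) and fdhD (0.26) were not called. The families were not tested there. Of 8 ccm genes, for cytochrome c maturation, 5 fell (median -0.91, camera adjusted p = 0.0378, and adjusted p = 0.746 with an estimated correlation). The other families past the test were par (4 of 4 fell, camera adjusted p = 0.0326, and adjusted p = 0.746 with an estimated correlation) and sha (3 of 5 rose, camera adjusted p = 0.0262, and adjusted p = 0.746 with an estimated correlation). In the mutant against the wild type at day 2, all 4 mdc genes of malonate decarboxylase fell (median -3.13, camera adjusted p = 0.0124, and adjusted p = 0.809 with an estimated correlation). Against the wild type of day 1, mdcC, mdcG and mdcD were not called. Against the wild type with ammonium, 12 of 17 pil genes, of type IV pili, rose in the mutant (median 2.02, camera adjusted p = 0.00763, and adjusted p = 0.739 with an estimated correlation). Also past the test there were ccm (7 of 8 rose), opr (5 of 6), par (4 of 4) and pyr (7 of 9), and all members of aco, fdh, glg, hut, mdc, pqq and sha fell. Their camera adjusted p was 0.0393 or below, and adjusted p = 0.682 with an estimated correlation. Against the earlier ammonium libraries, mdcG (log2 change 0.28), mdcC (-0.009) and fdhD (0.34) were not called in the mutant. There hutU (-2.27) and hutI (-2.20) were still called lower.

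Among ammonium libraries, day 2 differed from the mean of 15 hours and day 1 by 858 genes higher and 719 lower (limma). ibpB was higher by 5.70 and iscS by 3.68 on the log2 scale, and glnA was lower (-2.67, adjusted p = 0.0177). nifA (1.43, adjusted p = 0.0125) and nifL (1.05, adjusted p = 0.0170) were also higher. nifH (1.33, adjusted p = 0.0981), nifD (1.12), nifK (-0.063) and amtB (0.155) were not called. The locus tag Avin_55180 was listed at 0 in 7 libraries (6 of the mutant and 1 with ammonium) and lay between 324752 and 1070000 FPKM in the others.

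One hypothesis was that ammonium released by the mutant acts on its cells as added ammonium does, in which case the change of the mutant at day 2 would correlate positively across genes with the early change of the wild type with ammonium (15 hours and day 1 against day 1). The correlation was -0.228 (Spearman -0.376, and -0.247 to -0.144 with 1 library left out), from libraries that the comparisons do not share. The predicted positive sign was not seen. The nif genes, higher in the mutant and lower with ammonium, were not left out of it. The early ammonium change also held few called genes (9), and ammonium at day 2 was not used. The test therefore cannot decide the hypothesis. Genes are not independent replicates, and an effect of released ammonium may be hidden by others.

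Regrouping the samples asked how often other splits of the libraries give as many calls over all times. The splits treat libraries as exchangeable, though they may not be separate cultures and the arms hold different times. A small share therefore does not part strain or medium from time or culture. For mutant against wild type 1 of 100 splits, the real one, was as large (651 genes, highest other split 393). For wild type with against without ammonium, 3 of 100 splits, the real one included, were as large. The real split called 267 genes (18 without ammonium day 2 replicate 2) and the highest other 655, which set the ammonium libraries of 15 hours and day 2 and wild-type day 2 replicate 1 against the rest and points to a structure of the samples. For mutant against wild type with ammonium 1 of 100 splits, the real one, was as large (1674 genes, highest other 477).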
